A study of Mus musculus with 18 samples.

How the data were processed

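RNA sequencing libraries from the liver of wild-type C57BL/6 mice were compared in 3 groups of 6, 18 libraries in all. Sham mice had a laparotomy under anaesthesia and no clamping. In the IR group the portal triad was clipped for 1 h, which made about 70% of the liver ischemic, and the tissue was reperfused for 6 h. The IR-Ori group had the same ischemia and reperfusion and was given oridonin, a diterpenoid from the herb Isodon rubescens. The dose, route and time of the oridonin treatment are not given in the sources used here.

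Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1 and aligned with HISAT2 2.2.1 to the mouse genome build GRCm39, and DESeq2 is named without a version or a purpose. The counting tool and the annotation release are not given in the sources used here. The deposited table holds, for each library, a whole-number read or fragment count per Ensembl gene, which the authors did not scale. It also holds FPKM made by the authors, counts divided by exonic gene size and by the library total. Dividing each count by the gene size and by the sum of the library's counts returned 100% of the deposited FPKM within a tolerance of 0.0051, so the total behind the FPKM includes the counts of the mitochondrial genes. FPKM of nuclear genes therefore fall where the mitochondrial share of a library rises. The table has 56691 genes, 37 of them on the mitochondrial chromosome. Gene positions, sizes and strands are those of the table. Biotypes and transcript GC content came from GENCODE M21, an annotation of an older genome build, joined by gene identifier alone, and 52073 of the 56691 identifiers were found there.

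Total counts ranged from 12449529 to 19798188 per library. No 2 of the 18 columns of counts were identical, and the lowest chi-square per gene between 2 libraries of a group, over genes with at least 20 counts, was 16.0, far above the value near 1 of a library sequenced again. The counts of a gene include counting error, but the spread between libraries was larger, with a common biological coefficient of variation of 0.3984.

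Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with the 3 groups (minimum count 10, minimum total count 15), which left 14595 of 56691. Library sizes were scaled by the trimmed mean of M-values, and 1 quasi-likelihood negative binomial model with a group factor was fitted to all 18 libraries, which leaves 15 residual degrees of freedom. The 3 pairs of groups were compared by two-sided quasi-likelihood F tests, with Benjamini-Hochberg adjustment over the 14595 genes within a comparison and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are given as the mean and standard deviation of the deposited FPKM over 6 libraries. The plan made before the data were examined foresaw limma on log2(FPKM + 1), or edgeR in its place if the table also held counts. It did, so edgeR was used, and limma 3.58.1 on log2(FPKM + 1) for genes with an FPKM of at least 1 in at least 6 libraries became an alternative.

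A total of 45 lists of genes (cell type markers, pathways and gene families) were fixed before the data were examined, and 41 of them had at least 3 members tested. For each, members past the threshold were counted, once adjusted over all genes and once adjusted over the list alone. Lists were tested against all other genes with camera in limma at a preset correlation between genes of 0.01, adjusted over the 41 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without regard to other genes, were run beside it. The list score of a library is the mean log2(FPKM + 1) of the members, and scores were compared by an exact two-sided permutation test of 6 libraries against 6, whose 924 splits cannot give a p below 0.002165.

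The genes named in the text follow a rule set before the data were examined. It takes the 10 protein-coding genes with the largest fold changes each way among those past the threshold, with a mean FPKM of at least 1 in the higher group and no overlap between the groups in any of the 36 pairs of libraries. Where none passed, the 5 with the smallest p were taken as not passing. It adds up to 4 members of each list with the smallest p, and 10 genes fixed by name. A gene that the rule takes in 1 comparison may also be given in the others. A few further members were named after their values were seen, to complete short lists.

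The difference between IR-Ori and IR and the difference between IR and sham both contain the IR libraries, with opposite signs, so that opposite signs arise from noise alone. Their relation was therefore also computed with the 6 IR libraries split into 3 and 3 over the 20 ordered splits, one part used in each difference. It was also set against 100 simulations in which the counts of all 18 libraries were drawn from the fitted model with the IR-Ori means set to those of IR. A first version of the simulation drew only the IR-Ori libraries and was replaced, since it left out the noise shared through the IR libraries.

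The steps were tested on simulated data with known changes, made from the means and spreads of this table. At a true 4-fold change 86% of the changed genes were found for IR against sham, 89% for IR-Ori against IR and 72% for IR-Ori against sham. At a true 2-fold change the shares were 34%, 31% and 26%. Of 113, 233 and 97 calls in the simulated comparisons, 2, 11 and 0 were false. All 10 lists of 15 genes with a doubled level were found, and 1 of the 90 other lists was called. The simulated genes were drawn independently, while the estimated correlation in IR against sham was 0.737 in the immediate early list and 0.657 in the heat shock list. The simulated lists therefore do not measure how often lists of correlated genes are called falsely. Nor do the simulated genes follow the mitochondrial share of a library, which moves many nuclear genes together. The shares found and the false calls above thus hold for independent genes and may not hold for the real counts.

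Alternatives set before the data were examined were another pseudocount, no filter, a stricter filter on FPKM, median-of-ratios scaling, quantile normalization, fits of only the groups compared, the replicate number as a block, array quality weights, an exact rank-sum test, DESeq2 1.42.0 and leaving out each library in turn. The pseudocount, quantile normalization, array weights and the rank-sum test were run on FPKM of the genes with an FPKM of at least 1 in at least 6 libraries, the first 3 with limma, so that they stand beside limma on FPKM. The rank-sum test called 0 genes in each of the 3 comparisons, and so did limma on FPKM in IR-Ori against sham. A 0 from these for the members of a list was thus fixed and is not given. After the data were examined, limma on FPKM and settings that address the mitochondrial share of the libraries were added. Tables were joined and figures drawn with Python 3.11.15. Lists with fewer than 3 members tested were given no list test, and genes under the filter were left out because their counts were too low to test.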

Results

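Gene expression was measured by RNA sequencing in the liver of wild-type C57BL/6 mice, in 3 groups of 6 libraries: sham surgery, ischemia and reperfusion (IR), and ischemia and reperfusion with oridonin (IR-Ori). Libraries held 12755980 to 19798188 counts in sham, 12449529 to 16625908 in IR and 12770586 to 16536186 in IR-Ori. The labels do not say whether the libraries of a group come from separate animals, so the p-values measure the spread between these samples. Mitochondrially encoded genes took 21.9 ± 12.9% of the counts in sham, 19.2 ± 12.99% in IR and 27.1 ± 6.60% in IR-Ori (mean ± SD, n = 6 each). No difference lay past the spread (two-sided exact permutation, n = 6 each, p = 0.712 for IR against sham, 0.212 for IR-Ori against IR and 0.370 for IR-Ori against sham). Within the groups, 3035 of the 14579 nuclear genes tested were higher and 3535 lower in libraries with a larger mitochondrial share (edgeR).

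**Figure D1:**
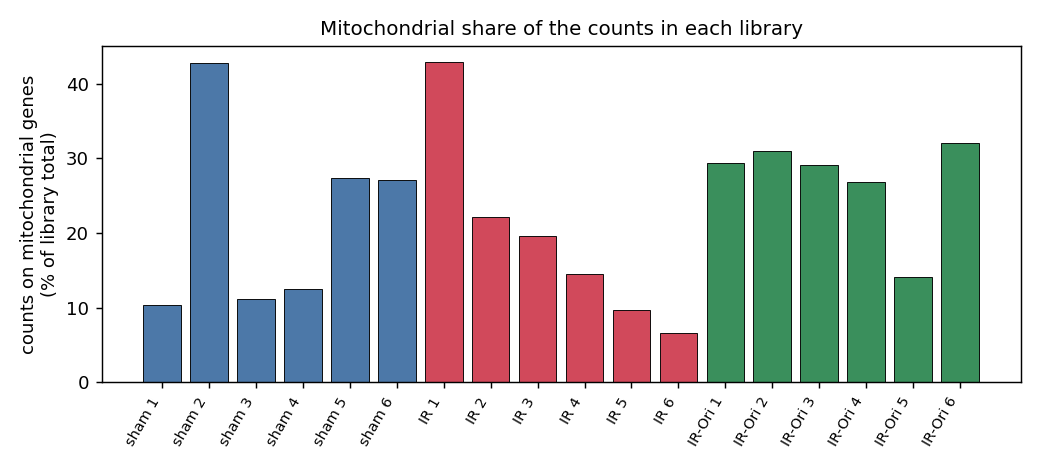
Percent of all counts on mitochondrially encoded genes (y axis) in each of the 18 libraries (x axis), 1 bar per library, coloured by group. The lowest share was 6.52% in IR 6 and the highest 42.9% in IR 1.

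The comparison of IR with sham addresses what ischemia and reperfusion do to liver expression. Chaperone genes and immediate early genes rose. Hspa1a, an inducible chaperone (ENSMUSG00000091971, GRCm39 chromosome 17, 35188166 to 35191132, minus strand, protein-coding), was at 60.1 ± 52.7 FPKM in IR and 0.35 ± 0.404 in sham (mean ± SD, n = 6 each), a log2 fold change of 7.40 ± 0.81 (SE; adjusted p = 0.000102). Hspa1b, its near-identical neighbouring copy (ENSMUSG00000090877), rose by 5.81 ± 0.76, and how reads divide between both copies is uncertain. The small heat shock protein Hspb1 rose by 4.88 ± 0.57, the chaperone Hsp90aa1 by 2.78 ± 0.50 and the co-chaperone Dnajb1 by 4.29 ± 0.80. Of 14 heat shock genes, 11 rose and 0 fell. In the heat shock list 13 rose adjusted over the list alone (camera adjusted p = 3.66e-15, adjusted p = 0.0881 with an estimated correlation). Within the groups, 6 of these 14 genes were lower where the mitochondrial share was larger (adjusted p = 0.0411, adjusted p = 0.893 with an estimated correlation).

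Atf3, a stress-induced transcription factor (ENSMUSG00000026628, chromosome 1, 190902493 to 190950236, minus strand, protein-coding), rose by 7.15 ± 1.00 (SE of the log2 fold change, n = 6 each, adjusted p = 0.000637). The transcription factors Klf6 and Jun rose by 4.37 ± 0.65 and 4.36 ± 0.70, and Ier3, an early response gene, by 2.74 ± 0.33. Of 18 immediate early and AP-1 genes, 15 rose and 0 fell. In the immediate early list 18 rose adjusted over the list alone (camera adjusted p = 5.02e-16, adjusted p = 0.121 with an estimated correlation). The IR libraries did not respond alike. The heat shock score was 4.82 to 5.10 in IR 1 to IR 3 and 6.57 to 7.53 in IR 4 to IR 6 (3.44 to 3.91 in sham). The immediate early score was 3.17 to 3.74 and 4.28 to 6.77 (1.92 to 2.56 in sham). IR 4 to IR 6 had a mitochondrial share under 15%. Leaving out single libraries does not show this split. The size of several rises also rested on IR 6. Without it the log2 fold change of Fosb was 4.22 instead of 8.42, of Fos 3.13 instead of 5.22, of Egr1 3.17 instead of 4.98, of Dnajb1 2.77 instead of 4.29 and of Maff 2.22 instead of 3.76, and only Maff, a small Maf transcription factor, no longer passed (adjusted p = 0.0592).

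Genes of the matrix and of repair rose with them. Thbs1 and Ccn1, matricellular proteins that act on cell adhesion, both rose by 3.93 (SE 0.55 and 0.64, n = 6 each), the urokinase receptor Plaur by 3.34 ± 0.62 and the hyaluronan receptor Cd44 by 1.27 ± 0.25. Of 17 matricellular, fibrinolysis and repair genes, 13 rose and 0 fell. In the matricellular list 15 rose adjusted over the list alone (camera adjusted p = 1.34e-15, adjusted p = 0.0480 with an estimated correlation). Sprr1a, an envelope protein induced by stress, rose by 6.86 ± 1.01, Ch25h, a cholesterol hydroxylase of activated myeloid cells, by 6.01 ± 0.94 and the hyaluronan-binding Tnfaip6 by 5.41 ± 0.79.

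Chemokines and myeloid markers rose as well. Cxcl2, a neutrophil-attracting chemokine (ENSMUSG00000058427, chromosome 5, 91051730 to 91053797, plus strand, protein-coding), went from 0.222 ± 0.224 to 7.01 ± 2.42 FPKM (log2 fold change 4.98 ± 0.67, n = 6 each, adjusted p = 0.000539). The monocyte chemokines Ccl2 (ENSMUSG00000035385) and Ccl7 rose by 3.85 ± 0.42 and 3.99 ± 0.55 and the cytokine Il1b (ENSMUSG00000027398) by 2.62 ± 0.45. Of 14 inflammatory cytokines, chemokines and adhesion molecules, 8 rose and 0 fell. In the cytokine list 9 rose adjusted over the list alone (camera adjusted p = 2.70e-14, adjusted p = 0.0233 with an estimated correlation). The neutrophil genes Clec4d, Il1r2, Retnlg and S100a9 rose by 3.92 ± 0.61, 4.58 ± 0.74, 3.49 ± 0.57 and 3.54 ± 0.58, and 10 of 11 neutrophil markers rose. In the neutrophil list 10 rose adjusted over the list alone (camera adjusted p = 1.49e-14, adjusted p = 0.0661 with an estimated correlation). The myeloid lectin Chil3 (ENSMUSG00000040809) rose by 4.67 ± 0.57, the coagulation factor chain F13a1 by 4.19 ± 0.53 and the integrin Itgam by 2.32 ± 0.33, among 7 of 10 monocyte and recruited macrophage markers. In the monocyte list 9 rose adjusted over the list alone (camera adjusted p = 4.16e-13, adjusted p = 0.0146 with an estimated correlation). None of the 12 markers of resident Kupffer cells was called (camera adjusted p = 0.798), neither at an unadjusted p nor by DESeq2 or limma. Clec4f stood at 19.9 ± 3.90 FPKM beside 24.8 ± 7.74 in sham (adjusted p = 0.405). The 7 B cell markers were lower as a list (camera adjusted p = 0.00992, adjusted p = 0.430 with an estimated correlation), with 0 called (2 at an unadjusted p and 0 by DESeq2 and limma).

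Feedback genes of NF-kB signalling also rose. They were Tnip1 (1.21 ± 0.27, n = 6 each), Tnfaip3 (2.10 ± 0.48), Nfkbib (1.15 ± 0.26), Relb (1.16 ± 0.28) and Rel (1.39 ± 0.40), 5 of 14 genes. In the NF-kB list 8 rose adjusted over the list alone (camera adjusted p = 1.01e-06, adjusted p = 0.0867 with an estimated correlation). The call of Rel was lost without any 1 of the 6 sham libraries, IR 4 or IR 6 (adjusted p up to 0.128), and its log2 fold change was 0.66 without IR 6. Of 16 inflammasome and pyroptosis genes, 2 rose, Il1b and the pyrin gene Mefv (2.39 ± 0.61, adjusted p = 0.0565 without IR 4), and Nlrp3 was added to them adjusted over the list alone, 3 in all (camera adjusted p = 0.134). The inflammasome sensor Nlrp3 went from 0.197 ± 0.104 to 0.46 ± 0.172 FPKM and did not pass (log2 fold change 1.20 ± 0.41, adjusted p = 0.0789; 0.0429 without IR 3). The cytokine Tnf (0.91 ± 0.60, adjusted p = 0.383) and the chemokine Cxcl1 (1.28 ± 0.70, adjusted p = 0.278) did not pass.

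Genes of cell stress rose in part. The antioxidant gene Srxn1 rose by 3.83 ± 0.55 (n = 6 each), the cystine transporter Slc7a11 by 5.12 ± 0.86, the glutathione transferase Gsta1 by 3.56 ± 0.68, the heme oxygenase Hmox1 by 3.21 ± 0.71 and Gclc, of glutathione synthesis, by 1.88 ± 0.42. They were among 7 of 22 NRF2 and antioxidant genes that rose. In that list 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.429 with an estimated correlation). Nqo1, a quinone reductase, did not pass (0.27 ± 0.39, adjusted p = 0.724). Of 22 hypoxia and glycolysis genes, 7 rose, among them the glycolytic Pkm (1.59 ± 0.29) and the glucose transporter Slc2a1 (1.32 ± 0.27), and 1 fell, the kinase Pdk1 (-1.18 ± 0.33). For hypoxia 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000129, adjusted p = 0.259 with an estimated correlation). In both lists 8 of 22 genes were lower where the mitochondrial share was larger (adjusted p = 0.0371 and 0.0244, adjusted p = 0.893 with an estimated correlation for both). The unfolded protein and integrated stress response genes Ppp1r15a (2.39 ± 0.46), Chac1 (3.16 ± 0.68), Hspa5 (1.58 ± 0.36), Ddit3 (1.38 ± 0.40) and Trib3 (1.23 ± 0.38; named after its value was seen) rose, 5 of 16. In the unfolded protein list 7 rose adjusted over the list alone (camera adjusted p = 4.40e-05, adjusted p = 0.116 with an estimated correlation). Without IR 6 the log2 fold change was 1.59 for Ppp1r15a, 2.07 for Chac1 and 0.71 for Ddit3. The call was lost for Ddit3 without sham 1, sham 3, sham 4, sham 5, sham 6, IR 4 or IR 6 (adjusted p up to 0.137), for Trib3 without sham 1, sham 2, sham 4, sham 5, sham 6, IR 4, IR 5 or IR 6 (up to 0.136) and for Pdk1 without sham 1, sham 4, IR 2, IR 4 or IR 5 (up to 0.0778).

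Secreted acute phase genes rose, with the plasma protein genes Orm2 (2.68 ± 0.50, n = 6 each), Orm1 (1.47 ± 0.40) and Orm3 (2.60 ± 0.77), Saa3 (2.24 ± 0.53) and the siderophore-binding Lcn2 (2.78 ± 0.85), 5 of 23. In the acute phase list 9 rose adjusted over the list alone (camera adjusted p = 1.26e-06, adjusted p = 0.343 with an estimated correlation). Saa1 went from 176 ± 202 to 835 ± 514 FPKM and did not pass (2.17 ± 0.82, adjusted p = 0.112). The call was lost for Orm1 without sham 2, sham 3, sham 5 or IR 4 (adjusted p up to 0.0683), for Orm3 without IR 2, IR 4, IR 5 or any sham library but sham 1 (up to 0.0926) and for Lcn2 without any library but sham 6 and IR 6 (up to 0.102).

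Fatty acid synthesis genes and single genes of bile acid and glycogen metabolism fell. Cyp7a1, the first enzyme of bile acid synthesis (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633, minus strand, protein-coding), went from 33.2 ± 24.1 to 3.82 ± 1.35 FPKM (log2 fold change -3.14 ± 0.57, n = 6 each, adjusted p = 0.00311). Ppp1r3b, a glycogen-targeting phosphatase subunit (ENSMUSG00000046794, chromosome 8, 35842893 to 35855293, plus strand, protein-coding), went from 34.7 ± 13.8 to 7.18 ± 3.73 FPKM (-2.30 ± 0.39). Of 19 bile acid genes 2 fell, Cyp7a1 and the reductase Akr1d1 (-1.37 ± 0.39), the same 2 adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.144 with an estimated correlation). The lipogenic regulator Srebf1 (-1.60 ± 0.34), the synthase Fasn (-2.17 ± 0.48) and the pyruvate kinase Pklr (-1.65 ± 0.37) were among 6 of 13 fatty acid synthesis genes that fell. In the fatty acid synthesis list 8 fell adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.160 with an estimated correlation). Of 21 cholesterol synthesis genes 3 fell, Acat2 (-1.33 ± 0.38), Mvk (-1.14 ± 0.34) and Fdft1 (-1.53 ± 0.46). In the cholesterol synthesis list 11 fell adjusted over the list alone (camera adjusted p = 6.18e-08, adjusted p = 0.343 with an estimated correlation). Within the groups 11 of the 21 were lower where the mitochondrial share was larger (adjusted p = 0.0215, adjusted p = 0.893 with an estimated correlation).

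Other genes that fell were Sema5b, a semaphorin (-4.43 ± 1.13, n = 6 each), Igfbp5, a growth factor-binding protein (-3.85 ± 0.52), Hsd3b2, a steroid dehydrogenase (-3.71 ± 0.68), Keg1 (-3.27 ± 0.58), Nrep (-2.83 ± 0.81), the nuclear receptor Nr1h5 (-2.76 ± 0.58), the kinase Dclk3 (-2.41 ± 0.73) and the adrenergic receptor Adra1b (-2.10 ± 0.48). The call was lost for Sema5b without IR 4 or IR 5 (adjusted p up to 0.0575), for Nrep without sham 2, sham 3, sham 5 or any IR library but IR 1 (up to 0.0933) and for Dclk3 without any sham library but sham 1, IR 2, IR 3, IR 4 or IR 5 (up to 0.112). Among the metabolic genes above it was lost for Akr1d1 without sham 1, sham 3, sham 4, sham 5, IR 4 or IR 5 (up to 0.0762). It was lost for Acat2, Mvk and Fdft1 without sham 1, sham 3, sham 4 or any IR library but IR 1 (up to 0.111), and for Mvk and Fdft1 also without sham 5. None of 13 hepatocyte secretory genes was called (camera adjusted p = 0.355), neither at an unadjusted p nor by DESeq2 or limma. Within the groups 5 of them were lower and 1 higher where the mitochondrial share was larger (adjusted p = 0.0489, adjusted p = 0.893 with an estimated correlation). Albumin (Alb) was at 15716 ± 2245 FPKM in IR and 20138 ± 7627 in sham (log2 fold change -0.42 ± 0.32, adjusted p = 0.462).

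In all, 806 of 14595 genes rose and 345 fell (edgeR), 70% of the calls higher. With limma 65.7% of 594 calls were higher on FPKM as deposited and 54.6% of 679 on quantile-normalized FPKM. Among all 14595 genes tested, whether called or not, 298 were higher and 165 lower in IR with no overlap between the groups, where chance gives 15.8 each way. Leaving out 1 library moved a count by more than 1.5 times: without sham 4 556 rose and 204 fell, without sham 5 535 and 193, without sham 6 514 and 304, without IR 1 919 and 634, without IR 4 448 and 119, and without IR 5 483 and 131. The mitochondrial share was under 15% in sham 1, sham 3, sham 4, IR 4, IR 5 and IR 6, among which 991 genes rose and 555 fell, while 14 rose and 0 fell among the other 6 libraries.

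**Figure D2:**
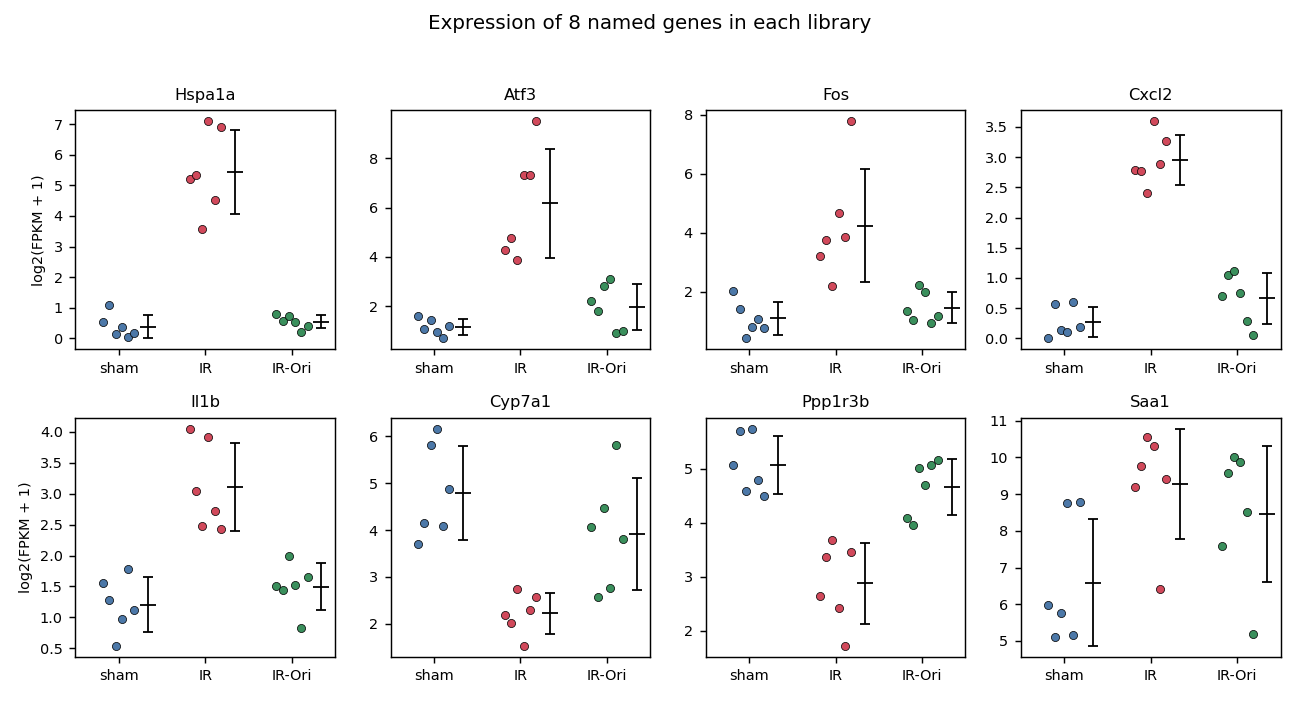
Level of 8 genes as log2(FPKM + 1) (y axis) in sham, IR and IR-Ori (x axis), with 1 point per library and bars for the mean ± SD of 6 libraries. Hspa1a was at 0.35 ± 0.404 FPKM in sham, 60.1 ± 52.7 in IR and 0.467 ± 0.212 in IR-Ori.

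The comparison of IR-Ori with IR addresses what oridonin changes in the reperfused liver. Chaperone genes and immediate early genes were lower with oridonin. Hspa1a was at 0.467 ± 0.212 FPKM in IR-Ori and 60.1 ± 52.7 in IR (mean ± SD, n = 6 each), a log2 fold change of -6.99 ± 0.79 (SE; adjusted p = 0.000354), and Hspa1b fell by 6.14 ± 0.77. Hspb1 (-4.13 ± 0.55), Dnajb1 (-4.75 ± 0.82), the chaperone Hsph1 (-4.37 ± 0.74) and Hsp90aa1 (-3.05 ± 0.51) fell too. Of 14 heat shock genes 12 fell and 0 rose. In the heat shock list 13 fell adjusted over the list alone (camera adjusted p = 4.73e-18, adjusted p = 0.0661 with an estimated correlation). With the 3 groups fitted together these genes tended to be lower where the mitochondrial share was larger, as given above. The mean share was 7.86 percentage points larger in IR-Ori than in IR. The heat shock score showed this relation mainly among the IR libraries, at 4.82 to 5.10 in IR 1 to IR 3 and 6.57 to 7.53 in IR 4 to IR 6. It was 3.79 in sham 2, with a share of 42.8%, and 3.67 in sham 1, with 10.3%. In IR-Ori it was highest, at 4.04, in IR-Ori 6, which had the largest share of that group, 32.0%.

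Atf3 (-5.67 ± 0.93, n = 6 each, adjusted p = 0.00404), Klf6 (-3.44 ± 0.62) and Ier3 (-2.34 ± 0.32) were lower with oridonin. So were Dusp4 (-4.94 ± 0.73) and Dusp5 (-4.49 ± 0.62), phosphatases that act on MAP kinases. Of 18 immediate early and AP-1 genes 13 fell and 0 rose. In the immediate early list 16 fell adjusted over the list alone (camera adjusted p = 9.49e-13, adjusted p = 0.226 with an estimated correlation). Within the groups 9 of these 18 genes were lower and 0 higher where the mitochondrial share was larger, though not as a list (camera adjusted p = 0.144, adjusted p = 0.893 with an estimated correlation). Jun, Fos, Egr1, Maff and Fosb fell by 3.55 ± 0.67, 4.66 ± 0.92, 4.32 ± 0.82, 4.41 ± 0.94 and 6.24 ± 1.36. Without IR 6 these falls were 2.25, 2.57, 2.51, 2.88 and 2.05, and that of Fosb did not pass (adjusted p = 0.0926).

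Matrix, chemokine and monocyte genes were lower as well. Sprr1a fell by 6.74 ± 1.01 (n = 6 each), Thbs1 by 3.57 ± 0.54 and Ccn1 by 3.90 ± 0.64, and 8 of 17 matricellular, fibrinolysis and repair genes fell and 0 rose. In the matricellular list 13 fell adjusted over the list alone (camera adjusted p = 1.07e-12, adjusted p = 0.0661 with an estimated correlation). Ccl2 fell by 2.95 ± 0.40, Ccl7 by 3.80 ± 0.54, Cxcl2 by 3.39 ± 0.60 and Il1b by 2.18 ± 0.44, among 7 of 14 inflammatory cytokines, chemokines and adhesion molecules. In the cytokine list 7 fell adjusted over the list alone (camera adjusted p = 1.06e-09, adjusted p = 0.0661 with an estimated correlation). Chil3 (-4.60 ± 0.57), F13a1 (-4.15 ± 0.53) and Itgam (-1.53 ± 0.32) were among 6 of 10 monocyte and recruited macrophage markers that fell. In the monocyte list 8 fell adjusted over the list alone (camera adjusted p = 1.11e-09, adjusted p = 0.0661 with an estimated correlation). Of 6 erythroid markers, genes of red blood cells, 0 were called by edgeR in IR against sham or in IR-Ori against IR, where DESeq2 called 2 lower and 2 were lower adjusted over the list alone. At an unadjusted p 3 were higher in IR and 2 lower with oridonin. As a list they were higher in IR (camera adjusted p = 0.0282, adjusted p = 0.413 with an estimated correlation). With oridonin their score was lower by 0.744 (n = 6 each, exact permutation, adjusted p = 0.0111), while camera did not pass (adjusted p = 0.0788). Whether blood content has a part in the myeloid changes was not tested. Of 3 replication-dependent histone genes, a list kept as a check of library preparation, 1 fell, 2 by DESeq2 and all 3 adjusted over the list alone. As a list they were lower (camera adjusted p = 0.00731, adjusted p = 0.257 with an estimated correlation, fry adjusted p = 0.0173). In IR against sham the same 3 genes had positive estimates and 1 was called higher, though they did not pass as a list (camera adjusted p = 0.298). A difference in library preparation between IR-Ori and IR was not tested and stays open. Of 11 neutrophil markers 3 fell, Clec4d (-2.37 ± 0.55), S100a9 (-2.08 ± 0.54) and the receptor Trem1 (-2.93 ± 0.72). In the neutrophil list 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.06e-05, adjusted p = 0.271 with an estimated correlation). The call was lost for Clec4d without IR 4, IR 5, IR-Ori 1, IR-Ori 3 or IR-Ori 6 (adjusted p up to 0.0682), for S100a9 also without IR-Ori 4 (up to 0.120) and for Trem1 without IR 4, IR 5, IR 6, IR-Ori 1, IR-Ori 2 or IR-Ori 6 (up to 0.0792).

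Inflammasome genes did not pass as a list. Il1b alone of 16 fell, and Nlrp3 was at 0.165 ± 0.0692 FPKM and did not pass (log2 fold change -1.48 ± 0.42, n = 6 each, adjusted p = 0.0537; 0.0250 without IR 3), though Il1b and Nlrp3 passed adjusted over the list alone (camera adjusted p = 0.523). Tnf (-0.97 ± 0.61, adjusted p = 0.325) and Cxcl1 (0.62 ± 0.69, adjusted p = 0.590) did not pass. Of 14 NF-kB feedback genes 1 fell, Relb (-1.05 ± 0.28), and 7 adjusted over the list alone (camera adjusted p = 0.00144, adjusted p = 0.271 with an estimated correlation). The call of Relb was lost without any library but IR 2 and IR 3 (adjusted p up to 0.113).

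Cell stress genes fell in part. Srxn1 (-3.21 ± 0.54, n = 6 each), Slc7a11 (-4.74 ± 0.84), Gsta1 (-2.70 ± 0.65) and Gclc (-1.82 ± 0.42) were among 6 of 22 NRF2 and antioxidant genes that fell. In that list 7 fell adjusted over the list alone (camera adjusted p = 0.000127, adjusted p = 0.312 with an estimated correlation). Hmox1 (-1.88 ± 0.67, adjusted p = 0.107) and Nqo1 (-0.51 ± 0.40, adjusted p = 0.430) did not pass. Of 22 hypoxia and glycolysis genes 5 fell, Pkm (-1.72 ± 0.29), Slc2a1 (-1.50 ± 0.27), Pfkp (-1.23 ± 0.32), Hk1 (-1.17 ± 0.32) and Adm (-1.72 ± 0.47; named here after its value was seen). In the hypoxia list 10 fell adjusted over the list alone (camera adjusted p = 4.73e-05, adjusted p = 0.265 with an estimated correlation). In both lists 8 of 22 genes were lower where the mitochondrial share was larger. Of 16 unfolded protein and integrated stress response genes 5 fell, Hspa5 (-1.68 ± 0.36), Chac1 (-2.98 ± 0.67), Ppp1r15a (-1.85 ± 0.45), Trib3 (-1.44 ± 0.38) and Sesn2 (-1.40 ± 0.38; named after its value was seen). In the unfolded protein list 7 fell adjusted over the list alone (camera adjusted p = 7.51e-05, adjusted p = 0.141 with an estimated correlation). Pkm, Slc2a1, Hspa5, Srxn1 and Slc7a11 passed whichever library was left out. Calls were lost for Gclc without IR 4, IR 5, IR-Ori 1 or IR-Ori 2 (adjusted p up to 0.0639), for Gsta1 without IR 4, IR 5, IR-Ori 2, IR-Ori 3, IR-Ori 4 or IR-Ori 6 (up to 0.108) and for Chac1 without IR 6, IR-Ori 3 or IR-Ori 6 (up to 0.0708). They were lost for Ppp1r15a without IR 4, IR 6 or any IR-Ori library but IR-Ori 4 and IR-Ori 5 (up to 0.0771) and for Pfkp without IR 4, IR 5, IR 6 or any IR-Ori library but IR-Ori 3 (up to 0.110). The same held for Adm without those 3 or any IR-Ori library but IR-Ori 4 (up to 0.132) and for Trib3 without those 3 or any IR-Ori library but IR-Ori 5 (up to 0.119). Hk1 (up to 0.131) and Sesn2 (up to 0.137) lost theirs without any 1 of IR 4, IR 5, IR 6 and the 6 IR-Ori libraries. Without IR 6 the log2 fold change was -1.05 for Ppp1r15a, -1.89 for Chac1 and -0.87 for Sesn2, and without IR 5 it was -1.73 for Gsta1.

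Several metabolic genes were higher with oridonin. Ppp1r3b went from 7.18 ± 3.73 FPKM in IR to 25.8 ± 8.76 in IR-Ori (log2 fold change 1.87 ± 0.38, n = 6 each, adjusted p = 0.0132). Zfand4, a zinc finger gene (ENSMUSG00000042213, chromosome 6, 116241183 to 116307263, plus strand, protein-coding), rose by 1.75 ± 0.30. The vesicle coat gene Sec31b rose by 1.54 ± 0.28, Tlcd1, of membrane lipid composition, by 1.01 ± 0.21 and the acyl-CoA synthetase Acsm5 by 0.97 ± 0.20. Cyp7a1 rose from 3.82 ± 1.35 to 19.4 ± 18.9 FPKM (2.36 ± 0.55), the 1 of 19 bile acid genes called (2 adjusted over the list alone, Cyp7a1 and Slco1a4; camera adjusted p = 0.0972). Of 13 fatty acid synthesis genes 2 rose, Srebf1 (1.35 ± 0.34) and Acaca (1.03 ± 0.24). In the fatty acid synthesis list 6 rose adjusted over the list alone (camera adjusted p = 0.000563, adjusted p = 0.312 with an estimated correlation). The fatty acid oxidation and PPARalpha list was instead lower (camera adjusted p = 0.0455, adjusted p = 0.858 with an estimated correlation, fry adjusted p = 0.445), with 2 of 22 genes called lower and 0 higher. Within the groups 12 of the 22 were lower and 0 higher where the mitochondrial share was larger (camera adjusted p = 0.00014, adjusted p = 0.893 with an estimated correlation). The mean share was larger in IR-Ori than in IR. Further rises were those of Rwdd2a (1.66 ± 0.38), the triokinase Tkfc (1.49 ± 0.35), the corepressor Tle2 (1.18 ± 0.30), the zinc finger gene Zfp809 (1.07 ± 0.27) and the monooxygenase Cyp2j6 (1.01 ± 0.22). Calls were lost for Cyp7a1 without IR 4 or IR 5 (adjusted p up to 0.0671), Srebf1 without IR 4, IR 5, IR 6, IR-Ori 1, IR-Ori 2, IR-Ori 4 or IR-Ori 6 (up to 0.0820), Acaca without IR 5, IR 6, IR-Ori 3 or IR-Ori 4 (up to 0.0648) and Rwdd2a without IR 4, IR 5 or IR-Ori 4 (up to 0.0568). They were lost for Cyp2j6 without IR 5 (0.0524), and without IR 4, IR 5, IR 6 or certain IR-Ori libraries for Tkfc (IR-Ori 2, IR-Ori 3, IR-Ori 4, up to 0.0739), Tle2 (IR-Ori 1, IR-Ori 3, IR-Ori 6, up to 0.0971) and Zfp809 (any but IR-Ori 5, up to 0.0832).

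Among acute phase genes no fall passed. Of 23, 7 had a positive estimate, and 0 were called by edgeR, DESeq2 or limma (1 lower at an unadjusted p, camera adjusted p = 0.335). Lcn2 was at 213 ± 196 FPKM in IR-Ori and 226 ± 182 in IR (log2 fold change 0.04 ± 0.79, n = 6 each, adjusted p = 0.982). Saa1 (-0.52 ± 0.79, adjusted p = 0.701) and Alb (0.27 ± 0.32, adjusted p = 0.610) did not pass. None of 21 cholesterol synthesis genes (camera adjusted p = 0.110) and 13 hepatocyte secretory genes (camera adjusted p = 0.839) was called by any of these tools or at an unadjusted p. Of 12 Kupffer cell markers edgeR and limma called 0 and DESeq2 1 higher (1 higher and 1 lower at an unadjusted p, camera adjusted p = 0.780).

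Altogether 87 genes rose and 439 fell with oridonin (edgeR), 16.5% of the calls higher. With limma 28.6% of 133 calls were higher on FPKM as deposited and 31.1% of 212 on quantile-normalized FPKM. With the mitochondrial share in the model 18 rose and 107 fell, among them Hspa1a (-6.91), Ccl2 (-2.95) and Ppp1r3b (1.86) and, at a smaller size, Atf3 (-3.67) and Hspa5 (-1.04). Of the genes named above as rising or falling with oridonin, 22 no longer passed in that model (adjusted p 0.05002 to 0.765). The log2 fold change was as large or within 0.05 for Clec4d (-2.47), Relb (-1.18), Pfkp (-1.22), Srebf1 (1.36) and Cyp2j6 (0.96). It was smaller for Dnajb1 (-3.13), Maff (-2.02), Jun (-2.55), Fos (-2.99), Egr1 (-2.76), Fosb (-0.85), Gclc (-1.35), Gsta1 (-2.23), Chac1 (-2.17), Ppp1r15a (-1.35), Trib3 (-0.95), Sesn2 (-0.87), Hk1 (-0.98), Adm (-1.40), Tkfc (1.23), Tle2 (0.92) and Zfp809 (0.84). Among the libraries over 15% mitochondrial 0 rose and 12 fell. Under 15% were IR 4, IR 5, IR 6 and IR-Ori 5, so that 1 library stood for IR-Ori, and no count is given there. Each library left out moved at least 1 of the counts of all libraries, 87 and 439, by more than 1.5 times: without IR 1 to IR 6 in turn 315, 172, 246, 13, 11 and 23 genes rose and 740, 667, 703, 160, 174 and 205 fell. Without IR-Ori 1 to IR-Ori 6 in turn 25, 46, 35, 45, 190 and 28 rose and 170, 207, 215, 261, 636 and 189 fell.

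**Figure D3:**
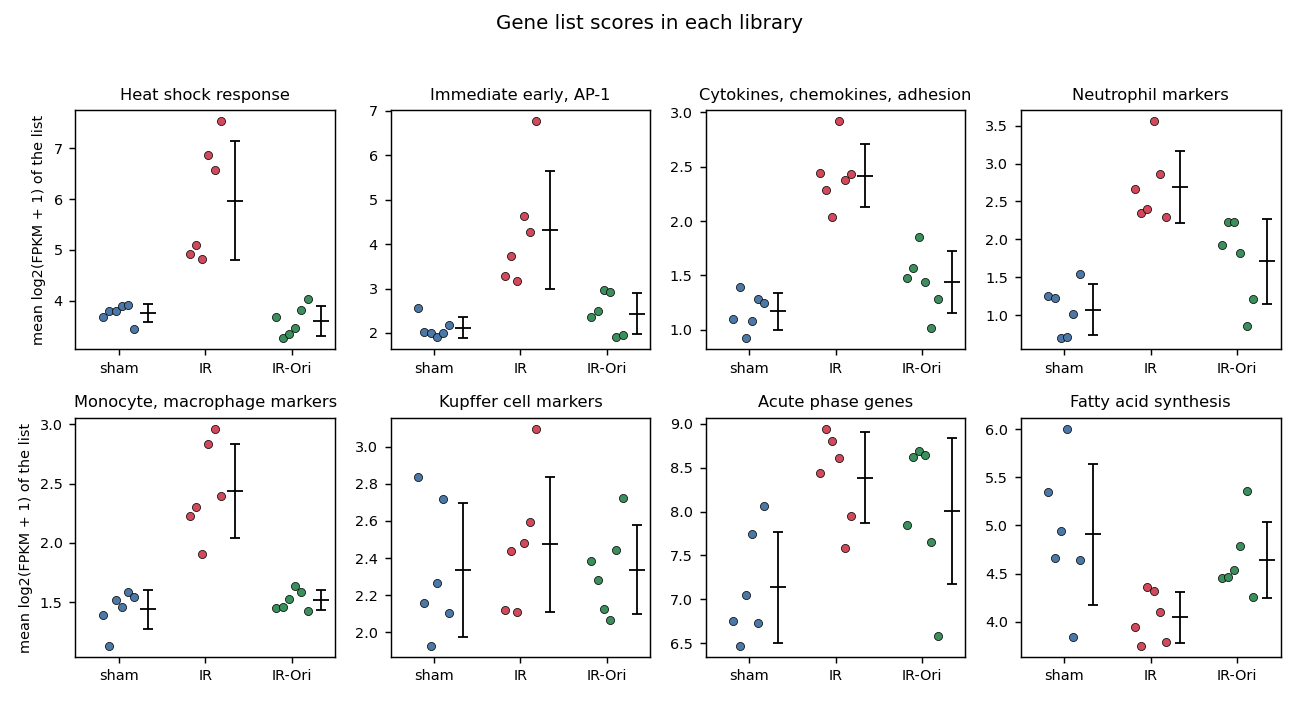
Mean log2(FPKM + 1) of the members of 8 gene lists (y axis) in sham, IR and IR-Ori (x axis), with 1 point per library and bars for the mean ± SD of 6 libraries. The heat shock list was at 3.75 ± 0.174 in sham, 5.97 ± 1.17 in IR and 3.59 ± 0.299 in IR-Ori, and the acute phase list at 7.14 ± 0.632, 8.39 ± 0.522 and 8.01 ± 0.829.

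The comparison of IR-Ori with sham addresses how far the treated liver stands from one without ischemia. Hspa1a was at 0.467 ± 0.212 FPKM in IR-Ori and 0.35 ± 0.404 in sham (mean ± SD, n = 6 each, log2 fold change 0.42 ± 0.71, adjusted p = 0.819), and Atf3 (1.48 ± 0.81), Cxcl2 (1.59 ± 0.65), Chil3 (0.07 ± 0.58), Cyp7a1 (-0.78 ± 0.52) and Ppp1r3b (-0.43 ± 0.37) did not pass either. Cfap69, a cilium gene, and Syt12, a synaptotagmin, had positive estimates of 2.63 ± 0.60 and 3.31 ± 0.77 and Igfbp5 a negative one of -2.08 ± 0.47, each with an adjusted p of 0.374. The same adjusted p was that of Plcb4 (1.35 ± 0.30), Cdh4 (2.51 ± 0.57), Cenpt (1.49 ± 0.35), Olfml1 (-1.39 ± 0.35), Scd2 (-1.05 ± 0.27) and Smoc2 (-0.98 ± 0.26). Srsf9 was at -0.68 ± 0.19 (adjusted p = 0.410). The fixed genes Nlrp3 (-0.28 ± 0.43), Il1b (0.44 ± 0.44), Tnf (-0.06 ± 0.64), Cxcl1 (1.898 ± 0.71), Hmox1 (1.33 ± 0.66), Nqo1 (-0.23 ± 0.40), Saa1 (1.65 ± 0.81) and Alb (-0.14 ± 0.32) did not pass.

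Of the 41 lists, 8 stood above and 9 below sham by camera at its preset correlation alone. Among the 8 were the acute phase genes and the neutrophil genes, the latter also lower with oridonin than in IR. So were 3 further lists of the 8: the immediate early and AP-1 genes, the cytokines and the NF-kB genes (against sham camera adjusted p = 0.0413, adjusted p = 0.718 with an estimated correlation, for each). None of 11 neutrophil markers passed over all genes (8 at an unadjusted p and 1 by DESeq2). In the neutrophil list 7 were higher adjusted over the list alone (camera adjusted p = 8.46e-07, adjusted p = 0.718 with an estimated correlation), with Il1r2 at 2.60 ± 0.72 (n = 6 each, adjusted p = 0.410). None of 23 acute phase genes passed (9 at an unadjusted p and 0 by DESeq2). In the acute phase list 4 were higher adjusted over the list alone, Lcn2 (2.81 ± 0.85), Orm2 (1.58 ± 0.48), Orm3 (2.39 ± 0.77) and Orm1 (1.17 ± 0.40), each with an adjusted p from 0.446 to 0.449 (camera adjusted p = 8.46e-07, adjusted p = 0.718 with an estimated correlation). Cholesterol synthesis genes were lower as a list (camera adjusted p = 1.02e-06, adjusted p = 0.718 with an estimated correlation), with 0 of 21 called (2 at an unadjusted p and 0 by DESeq2), and the mitochondrial share moved with this list as given above. Heat shock genes did not pass as a list (camera adjusted p = 0.428, with 0 of 14 called by edgeR or DESeq2 or at an unadjusted p).

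Over all genes edgeR called 0 higher and 0 lower (smallest adjusted p = 0.374; 926 and 534 at an unadjusted p), limma on FPKM and the rank-sum test 0, DESeq2 34 and 4, and limma with array weights 1865 and 2638. With single libraries left out edgeR still called 0. Genes at an unadjusted p then ran from 728 without IR-Ori 3 (edgeR, smallest adjusted p = 0.758) to 3304 without IR-Ori 5 (0.0725). Without sham 2 they were 3137 (0.171). The absence of calls does not show that the groups are alike. In the simulated counts 0% of genes with a true 1.5-fold change, 26% with a 2-fold and 72% with a 4-fold change were found. Those genes were drawn independently, without the mitochondrial share, so the real shares may differ.

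What oridonin changed was set against what IR had changed. Of the 806 genes higher in IR than in sham, 339 were lower in IR-Ori than in IR, among them Hspa1a, Atf3, Ccl2, Chil3 and Il1b. Of the 345 lower ones 50 were higher in IR-Ori, among them Ppp1r3b, Zfand4 and Cyp7a1. Independent calls would share 24.24 and 2.06, and simulated counts with IR-Ori at the level of IR shared 0.01 and 0.05 on average. Neither is a full measure of chance. Independent calls leave out that both comparisons share the IR libraries. The simulated genes were drawn independently, without the mitochondrial share that moves many genes together, so that few calls in IR-Ori against IR arise in them. With the mitochondrial share in the model 104 and 17 genes were called in opposite directions. Across the 1151 genes called in IR against sham the slope of the oridonin change on the IR change was -0.734 (-0.779 to -0.666 with each IR or IR-Ori library left out), and 98.8% had opposite signs. Both differences contain the IR libraries, and with these split 3 and 3 between them the slope was -0.571 on average (-0.870 to -0.232 over 20 splits) and the share 94.3% (79.3% to 100%). In the simulated counts, whose IR libraries were not split, they were -0.0891 and 66.4%. The simulated counts called 2174 genes on average in IR against sham instead of 1151, so their slope and share rest on other and more genes. With the mitochondrial share in the model the slope was -0.647. Orm1, Lcn2, Syt12 and Cfap69 rose in IR and stood in IR-Ori at log2 fold changes from IR of -0.30 ± 0.39, 0.04 ± 0.79, -0.21 ± 0.69 and 0.08 ± 0.55 (n = 6 each, adjusted p 0.656 to 0.982), and the rise of Orm1 and Lcn2 depended on single libraries as given above. These means near IR joined unlike libraries. IR-Ori 5 and IR-Ori 6 were at 0.37 and 0.16 FPKM for Syt12, 0.2 and 0.17 for Cfap69, 34.1 and 9.28 for Lcn2 and 1333 and 799.5 for Orm1, within or under the range in sham, while IR-Ori 1 to IR-Ori 4 were at 2.21 to 8.05, 0.98 to 2.86, 72.7 to 446 and 2372 to 3845. Of the latter only Lcn2 in IR-Ori 1 (72.7 FPKM) was also within the range in sham, which reached 87.6 in sham 6.

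**Figure D4:**
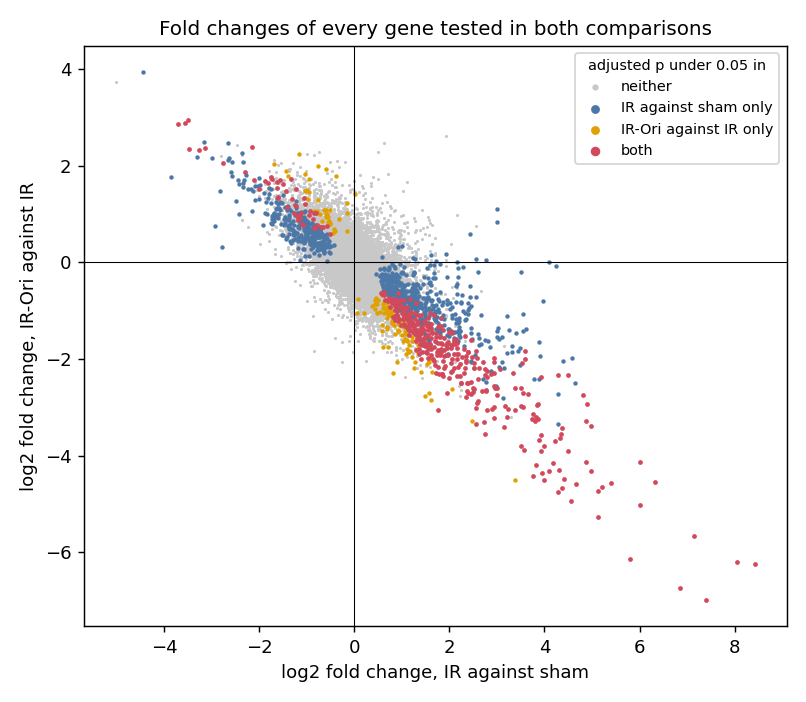
Log2 fold change of IR-Ori against IR (y axis) and of IR against sham (x axis) for the 14595 genes tested, 1 point per gene, coloured by the comparison in which the gene passed. Of the genes that passed in both, 339 rose and then fell and 50 fell and then rose.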

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

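The test of the genes called in IR-Ori against IR with the mitochondrial share in the model, and the counts within libraries above and below a share of 15%, were chosen only after the results were seen. In 426 groups of 6 libraries (120 genes, 20 lists and the library totals and shares), 1 library stood apart from the others of its group in 16 cases, by the gap to its neighbour relative to the range of the group. Chance gives about 1 in 20 groups, or 21.3 of 426, so the number of such cases is within chance.

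Fosb was at 67.53 FPKM in IR 6 and at 0.11 to 1.61 in the other 5 IR libraries, and Smoc2 at 0.73 in IR 5 beside 0.35 to 0.46. Saa1 was low in IR 5 (83.75 FPKM beside 586 to 1519), Rwdd2a in IR 1 (0.35 beside 0.74 to 0.99) and Alb in IR 1 (11680 beside 15550 to 18010). Among the sham libraries, Alb (6522 FPKM beside 18260 to 27700) and the score of the hepatocyte secretory genes (9.964 beside 11.09 to 11.65) were low in sham 2, where Ch25h (0.17 FPKM beside 0 to 0.05) and Relb (0.99 beside 0.4 to 0.56) were high. Hmox1 was high in sham 3 (39.63 FPKM beside 5.64 to 11.38), Hspb1 in sham 5 (22.9 beside 6.71 to 7.74) and Pdk4 in sham 1 (37.91 beside 0.51 to 2.59). In IR-Ori, Dusp4 was high in IR-Ori 3 (0.33 FPKM beside 0.03 to 0.1) and Maff low in IR-Ori 2 (0.62 beside 2.09 to 3.09). IR-Ori 5 had a low mitochondrial share (14.11% beside 26.81% to 32.03%) and a high score of the cholesterol synthesis genes (4.496 beside 2.688 to 3.23). Sham 2 and IR 1, where Alb was low, had the largest mitochondrial shares of all libraries, 42.8% and 42.9%, and FPKM are made from totals that include the mitochondrial counts.

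Within the groups, 3035 of 14579 nuclear genes were higher and 3535 lower where the mitochondrial share of a library was larger. Gene length is argued against, with a rank correlation of -0.0038 between exonic size and the slope of a gene on the share. The response to ischemia and reperfusion as the whole cause is argued against by slopes fitted within single groups, since sham had no ischemia. Their correlation across genes was 0.724 between sham and IR-Ori, 0.612 between sham and IR and 0.458 between IR and IR-Ori. The slopes in IR-Ori rest largely on IR-Ori 5 (share 14.11% beside 26.81% to 32.03%), which the correlation of sham with IR does not use. GC content of the transcripts cannot be told apart, with a rank correlation of 0.185 over 14328 genes that is neither near 0 nor large. Tissue state, cell integrity and the preparation of the libraries stay open, since the labels give no batch, and no biological explanation was tested.

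The second pattern is the set of genes called in IR-Ori against IR, whose groups differ in mean mitochondrial share by 7.86 percentage points. With the share in the model the log2 fold changes of the 526 called genes were at a median 0.773 times their value without it (quartiles 0.637 to 0.891), all 526 in the same direction, and 120 were still called. The median size went from 1.60 to 1.15 and the median standard error from 0.367 to 0.334. Why single calls ended was not tested. For IR against sham the median ratio was 0.965, and 1120 of 1151 genes were still called. A part of the IR-Ori difference cannot be told apart from the mitochondrial share, because the treatment may itself move the share and a regression on it would then remove part of the treatment effect. An effect of oridonin on the genes still called stays a hypothesis.

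For IR against sham 2 of 100 splits of the 12 libraries, the real one included, had as many calls (1151 genes in the real groups and 1467 in the highest other split). Only 100 of the 462 possible splits were run, which argues against chance but does not exclude it. The split with 1467, the real one with sham 1 and sham 4 exchanged for IR 1 and IR 2, set libraries with a mean mitochondrial share of 12.17% against others with 28.9%, and so follows the share more than the real groups do, a structure of the samples beside the groups. Within the libraries under 15% the real groups gave 991 genes higher and 555 lower, and within those over 15% 14 and 0. Of the 1546 genes called under 15%, 1366 (88.4%) had the same direction over 15%, with a slope of 0.405.

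For IR-Ori against IR 3 of 100 splits, the real one included, called as many genes (526 in the real groups and 1331 in the highest other split). Only 100 of the 462 possible splits were run. This argues against chance but does not exclude it, since other splits called more genes. In the split with 1331 IR 1, IR 2 and IR-Ori 1 to IR-Ori 4 had a mean share of 30.22% and the rest 16.06%, so it follows the mitochondrial share and points to a structure of the samples. Another, with 867 genes called, was the real grouping with IR 3 and IR-Ori 5 exchanged, its sides at 18.31% and 27.98%, and does not separate the share from the treatment. Within the libraries over 15% the real groups gave 0 genes higher and 12 lower (edgeR). The 4 libraries under 15% hold 1 of IR-Ori, so no count is given there. The median size of the log2 fold changes of the 526 genes was 0.758 over 15% and 1.98 under it. For IR-Ori against sham the splits decide nothing about chance, since any split calls at least the 0 genes of the real groups. There edgeR gave 926 higher and 534 lower at an unadjusted p and DESeq2 34 and 4, and the highest other split called 169.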

How the results depend on the processing

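The settings with limma on FPKM, the mitochondrial share in the model, the mitochondrial genes left out and libraries chosen by their share were chosen only after the results were seen. Among the genes called in IR against sham or in IR-Ori against IR that a setting also tested, none changed sign other than with the libraries chosen by a share of 15%. The settings on FPKM tested 862 of the 1151 and 392 of the 526, and the stricter filter 397 and 190. In IR against sham (806 higher and 345 lower) counts were 215 and 168 with genes at an FPKM of at least 5 (fewer genes tested) and 453 and 191 with the replicate number as a block. Limma on FPKM, which changes tool, input and the genes tested (11326) at once, gave 390 and 204. Within it a pseudocount of 0.1 gave 394 and 208 and quantile normalization 371 and 308. DESeq2 gave 705 lower, the mitochondrial share in the model 799 lower, the libraries over 15% mitochondrial 14 and 0 and those under 15% 555 lower, with 6 libraries on each side. In IR-Ori against IR (87 and 439) counts were 34 and 118 with the FPKM filter, 25 and 158 with only both groups fitted, 28 and 135 with the block, 449 and 886 with DESeq2 and 18 and 107 with the mitochondrial share in the model. Without the libraries over 40% mitochondrial they were 621 and 1088, and with those over 15% 0 and 12. The libraries under 15% hold 1 of IR-Ori, so no count is given for them. Limma on FPKM gave 38 and 95. Within it the pseudocount gave 28 and 76, quantile normalization 66 and 146 and array weights, which ran from 0.274 (sham 2) to 2.69 (IR 3), 62 and 199. In IR-Ori against sham (0 and 0 by edgeR; 926 and 534 at an unadjusted p) limma on FPKM also gave 0 and 0, with array weights 1865 and 2638, and DESeq2 34 and 4. The exact rank-sum test called 0 and 0 in IR against sham and in IR-Ori against IR (smallest adjusted p 0.0713 and 0.163). Across single libraries left out, the counts ran from 448 to 920 higher and 119 to 634 lower in IR against sham and from 11 to 315 and 160 to 740 in IR-Ori against IR. Where no reason is given, the cause was not tested. Replicate numbers were not taken to pair the samples, since only 6 of 18 pairs of the same number had a correlation over 0.1 after group means were removed (mean -0.0016), and 1 of 18 libraries correlated best with its own number in both other groups. Between IR and IR-Ori all 6 such correlations were positive (0.0124 to 0.418) and 4 were over 0.1, so a shared factor there is not excluded. Of the genes taken by the naming rule or named in the text, 42 lost their call in IR-Ori against IR with the block, and 30 in IR against sham. Of the 41 lists, 16 were higher and 6 lower in IR against sham, 2 and 15 in IR-Ori against IR and 8 and 9 in IR-Ori against sham. With an estimated correlation these were 3 and 0, 0 and 0, and 0 and 0. Fry gave 13 higher and 2 lower in IR against sham, 0 and 15 in IR-Ori against IR and 0 and 0 in IR-Ori against sham. The exact test of list scores, adjusted over the lists, gave 14 and 2, 1 and 11, and 0 and 0. Camera with the mitochondrial share in the model gave 14 and 8, 6 and 15, and 4 and 4. The mean of the mitochondrially encoded genes turned, by the construction of that model, to -0.0869 in IR-Ori against IR and -0.0408 in IR-Ori against sham, and Ddit3 in IR against sham to -0.0038 with the libraries over 15% mitochondrial. With the IR libraries split 3 and 3 the slope of the oridonin change on the IR change was -0.571 on average (-0.870 to -0.232), beside -0.647 with the mitochondrial share in the model, and the percent of opposite signs was from 94.3 to 100 across settings, 94.3 being the mean of splits that ran from 79.3 to 100. Of the named genes, 74 of 100 kept their call in IR against sham and 40 of 70 in IR-Ori against IR whichever library was left out. What depth limits was not tested by thinning the counts, and the filter on counts left Il6 untested.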

Other observations

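The test of the acute phase genes against the heat shock and AP-1 genes and the clock genes Dbp and Nfil3 were chosen only after the results were seen. Endothelial markers rose in IR: the cadherin Cdh5 by 1.52 ± 0.30 (log2 fold change ± SE against sham, n = 6 each, adjusted p = 0.00534), the hyaluronan receptor Lyve1 by 2.46 ± 0.58 and the adhesion molecule Pecam1 by 0.97 ± 0.24, the 3 of 13 sinusoidal endothelial markers called (3 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.429 with an estimated correlation). Pecam1 did not pass without sham 6 or IR 4 (adjusted p up to 0.0599). The lipid droplet gene Plin2 rose in IR by 1.99 ± 0.47 and fell with oridonin by 2.39 ± 0.48, and Sox9, a transcription factor of bile duct cells, rose by 3.88 ± 0.67 and fell by 3.24 ± 0.64 (2.45 and 1.82 without IR 6). Sox9 is 1 of 9 cholangiocyte markers, which were lower with oridonin as a list (camera adjusted p = 0.0139, adjusted p = 0.141 with an estimated correlation; 4 lower adjusted over the list alone, 4 by DESeq2). With the mitochondrial share in the model the fall was 1.45 for Plin2 and 1.84 for Sox9, which no longer passed (adjusted p = 0.106).

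Circadian genes split in IR against sham. Hlf (-1.01 ± 0.23), Tef (-1.11 ± 0.29), Per3 (-2.14 ± 0.59) and Dbp (-1.61 ± 0.45) fell and Arntl (2.02 ± 0.52) and Nfil3 (1.69 ± 0.49; log2 fold change 0.78 without IR 6) rose, 6 of 17 clock genes (4 and 4 adjusted over the list alone, n = 6 each). The list had a median log2 fold change of 0.292 and a mean of 0.068, and its test pointed down without passing (camera adjusted p = 0.436). Of these genes only Hlf passed whichever library was left out. The others were lost without sham 5, IR 4 or IR 5 (Tef, adjusted p up to 0.0645), sham 3 or IR 6 (Arntl, 0.0697), sham 2, sham 4, sham 5, IR 2, IR 4, IR 5 or IR 6 (Per3, 0.0771), sham 3, sham 4, sham 5, IR 2, IR 4, IR 5 or IR 6 (Dbp, 0.0856) and any sham library, IR 4 or IR 6 (Nfil3, 0.149). The time of day at which tissue was taken is not given in the sources used here.

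The metallothioneins Mt1 and Mt2 were at 483 ± 382 and 369 ± 305 FPKM in sham, 1696 ± 737 and 1512 ± 536 in IR and 1820.1 ± 1381 and 1355 ± 1150 in IR-Ori (mean ± SD, n = 6 each), and passed against sham adjusted over the list alone, but not over all genes (adjusted p from 0.0833 to 0.485). The cytokine Il6 had too few counts to be tested, with 3 to 15 counts in each IR library, 0 or 1 in sham and 0 to 5 in IR-Ori.

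Oridonin may leave the acute phase genes high while the heat shock and AP-1 genes return towards sham, although the AP-1 list still stood above sham in IR-Ori by camera (adjusted p = 0.0413, adjusted p = 0.718 with an estimated correlation). The acute phase score minus the mean of the other 2 scores was 3.25 ± 1.59 in IR and 4.99 ± 0.791 in IR-Ori (n = 6 each; two-sided exact permutation p = 0.0346), and with the mitochondrial share regressed out p was 0.0476. The first did not pass without IR 4, IR 5, IR 6, IR-Ori 1, IR-Ori 2, IR-Ori 3, IR-Ori 4 or IR-Ori 5 (exact p from 0.0519 to 0.0736, 5 libraries against 6), and the second passed only without IR 2, IR 3 or IR-Ori 6 (exact p from 0.0584 to 0.0931 without any other library). Neither test decides. In IR the difference of scores stood 0.955 below sham, which did not pass (exact permutation p = 0.212, n = 6 each, and 0.208 with the share regressed out). If the acute phase genes did rise less in IR, the difference of scores would also rise where all 3 lists returned to sham. Against sham the difference in IR-Ori was 0.786 higher and did not pass (exact permutation p = 0.0974, n = 6 each; 0.361 with the share regressed out), so acute phase genes that stay high cannot be told apart from the same return of all 3 lists, with the spread or the share of the libraries behind the rest. The acute phase score itself was 8.39 ± 0.522 in IR and 8.01 ± 0.829 in IR-Ori (exact permutation p = 0.361), which does not show that it did not fall. How reads divide among the similar Orm and Saa copies was not tested and stays open.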
